A study of Mus musculus with 6 samples.

How the data were processed

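RNA of 3 libraries of captured circulating tumour micro-emboli and of 3 libraries of 4T1 cells was extracted and amplified with an ultra low input kit, per the labels' protocols. The submitters' processing notes name HISAT2 2.0.4, Bowtie 0.12.2, edgeR and the mouse build mm8, with no role or order, and the counting tool and annotation are not given in the sources used here. The deposited table holds estimated counts per Ensembl gene for 56691 gene identifiers, and the authors' values are whole numbers that were not scaled to a fixed total. Low counts pile up at multiples of 4. In 4T1 replicate 1, for example, 956 genes had a count of 4, against 391 at 3 and 320 at 5. What produced this is not given in the sources used here. If one fragment was worth more than 1 count, counting error is larger than the deposited totals of 69178212 to 71595766 imply. The values were already whole, so no rounding was needed. The planned test had assumed plain counts and was kept, since edgeR takes estimated counts as well.

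Gene symbols were found for 52073 identifiers in a table of mouse gene names, and 4618 had no symbol. No coordinates are given, because identifiers and the named build come from different annotations. Each library was placed in its group by the description in its label. Genes with low counts were removed with the filterByExpr function, which left 16414 genes, and library sizes were scaled by TMM, with factors from 0.952 to 1.04. The quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 was fitted to all 6 libraries without a block, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The biological coefficient of variation was 28.1%. Standard deviations are over the 3 normalised CPM values of a group. CPM values of hepatocyte transcripts are shares of the library total.

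Before the data were examined, 28 gene lists, the tests and the rule for naming genes were fixed. The rule takes the 12 higher and 12 lower genes with the smallest p among those that passed, changed at least 2-fold, had no overlap between groups and had at least 10 CPM in the higher group, leaving out predicted genes and pseudogenes. It adds up to 4 members of each list with the smallest p, and Hif1a, Vegfa, Itga2b, Pf4, Ptprc, Epcam, Krt8 and F3. Other members of the lists are named where a count of 5 or fewer needed it, after their values were seen. The values of some members are not reported here. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the 28 lists, and again with a correlation estimated from the data and with fry. After the results were seen, 5 lists were added, for hepatocytes, YAP and TAZ targets, actin and SRF targets, serine and one-carbon metabolism, and lysosomes. They were adjusted over all 33 lists.

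The gene test was tested on simulated data for this comparison, with 16414 genes of which 200 were changed. The filter kept 15938, among them 199 of the changed genes. The test called 4 of 50 genes changed 1.5-fold, 30 of 50 changed 2-fold, 46 of 50 changed 4-fold and 47 of 50 changed 8-fold, and 7 of 15739 unchanged genes. The simulated libraries were independent draws, without close pairs of replicates, a replicate standing apart or low counts at multiples of 4. The share of false calls in the real data is therefore not given by this simulation. The alternatives were DESeq2 1.42.0 and its size factors, limma voom with quality weights, library totals alone, removal of mitochondrial and haemoglobin genes, no filter, a filter of 5 CPM in 3 libraries, a replicate block, a 2-fold minimum, and each library left out in turn. Chosen after seeing the data were counts divided by 4, both libraries numbered 1 left out, a batch term for those libraries, and the mean of the libraries numbered 2 and 3 as 1 sample.

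Before averaging, replicates were compared by a chi-square per gene on the counts divided by 4. It was 3.16 between 4T1 replicates 2 and 3 and 4.26 between CTM replicates 2 and 3, where sampling noise alone gives about 1, and 24.3 to 69.2 for the other pairs within a group. This does not show whether the close pairs are separate samples or repeats of one, since the divisor is assumed and amplification adds noise of its own. All 6 libraries were kept as separate samples, as the labels give them, and a fit with the mean of each close pair as 1 sample was added.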

Results

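Gene expression was measured by RNA sequencing in 6 mouse libraries. The first group, CTM, held 3 libraries of circulating tumour micro-emboli, clusters of tumour cells travelling in the blood, which were recovered with a microfluidic capture device from mice carrying breast cancer that had spread to the lung. The second group, 4T1, held 3 libraries of the cultured mouse mammary carcinoma line 4T1, whose titles name a low adherence culture. The deposited estimated counts summed to between 69178212 and 71595766 per CTM library and between 69640898 and 70703739 per 4T1 library. Between 20263 and 21370 genes had a count above 0 in a library. The labels do not say whether the 3 libraries of a group came from separate cultures or animals, so the p-values measure the spread between these libraries, which may be technical.

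The comparison asked how the RNA of captured clusters differs from that of the cultured line, and the series title directs it to hypoxia and platelets. The groups differed at once in growth in mice or in culture, in passage through blood and in capture. The design cannot tell these apart as causes. Genes of the response to low oxygen rose together in CTM. Adm, which encodes the vasodilator peptide adrenomedullin, was at 229 ± 39.4 normalised CPM in CTM and 12.1 ± 1.96 in 4T1 (SD, n = 3 each), an 18.8-fold difference. Vegfa, the vascular growth factor, was 6.27-fold higher, at 544 ± 128 against 86.8 ± 17.9 CPM (SD, n = 3 each). Ero1l, an oxidase of the endoplasmic reticulum, was 5.18-fold higher, at 5492 ± 196 against 1061 ± 27.9 CPM (SD, n = 3 each). The genes of DNA replication and mitosis moved the other way, all 28 of those tested being lower in CTM.

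Of the 16414 genes tested, 2323 were higher and 2252 lower in CTM at an edgeR quasi-likelihood adjusted p below 0.05, together 27.9% of the genes. A change of at least 2-fold was seen in 738 of the higher and 832 of the lower genes. At an unadjusted p below 0.05 there were 6691 genes. In 4072 genes all 3 CTM values lay above all 3 4T1 values and in 3861 they lay below, together 48.3% of the genes. Chance gives 10% if the libraries are independent, and more if replicates 2 and 3 of a group are repeats of the same sample. The first principal component of log2 CPM held 46% of the variance and parted the groups, and the second held 21.9% and parted 4T1 replicate 1 from the other libraries. Leaving out CTM replicate 2 lowered the counts to 1334 higher and 1208 lower, and leaving out both libraries numbered 1, a choice made after seeing the data, raised them to 4239 and 4340. The libraries numbered 2 and 3 of each group were far closer to each other than to the third, and with their mean counted as 1 sample, also a choice made after seeing the data, 276 genes were higher and 200 lower.

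**Figure D1:**
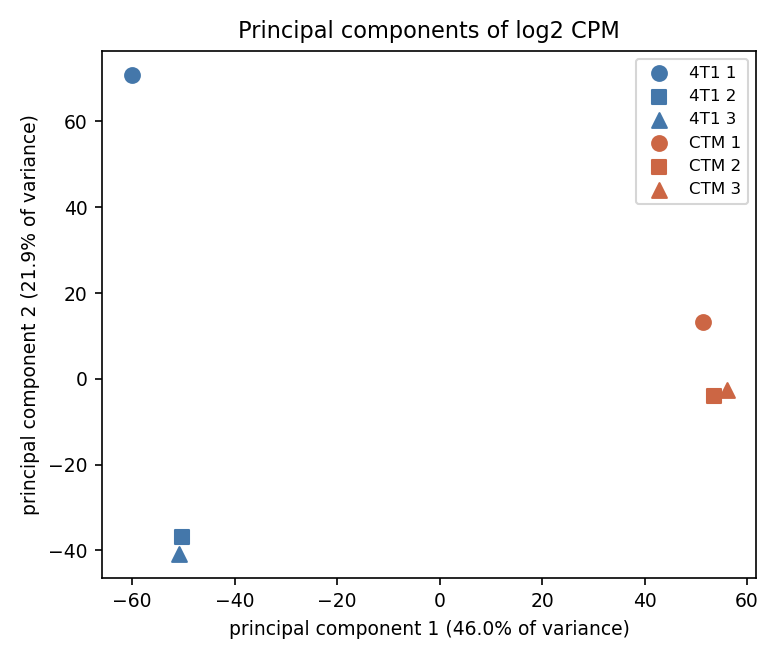
The first 2 principal components of log2 CPM, with one point per library, blue for 4T1 and orange for CTM, and the marker giving the replicate number. The 3 CTM libraries lie between 51.4 and 56 on the first component and the 3 4T1 libraries between -60 and -50.2, while 4T1 replicate 1 lies at 70.9 on the second.

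Of the 26 measured genes of the hypoxia response list, 23 rose, none fell and 3 did not pass the test, with a median log2 fold change of 1.80 (camera adjusted p = 3.37e-51 on the edgeR fit). Adjusted over the list alone, 24 passed. Among the risers were Ndrg1, a stress-responsive gene, at 6488 ± 963 against 952 ± 47.8 CPM (SD, n = 3 each), Higd1a, a mitochondrial protein induced by hypoxia, at 72.1 ± 6.11 against 10.9 ± 0.348, and P4ha1, a subunit of the collagen prolyl hydroxylase, at 882 ± 32.6 against 228 ± 18.1. The members that did not pass were Angptl4, Loxl2 and Pfkfb4. Of the 28 lists fixed before the data were examined, this was the only one to keep its call with an estimated correlation between genes (adjusted p = 0.0297 with an estimated correlation), and fry gave an adjusted p of 0.000189. Hif1a, which encodes the oxygen-regulated transcription factor subunit, was at 257 ± 33.8 CPM in CTM and 474 ± 355 in 4T1 (SD, n = 3 each; edgeR adjusted p = 0.196), with 884 CPM in 4T1 replicate 1 against 273 and 267 in the other two.

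**Figure D2:**
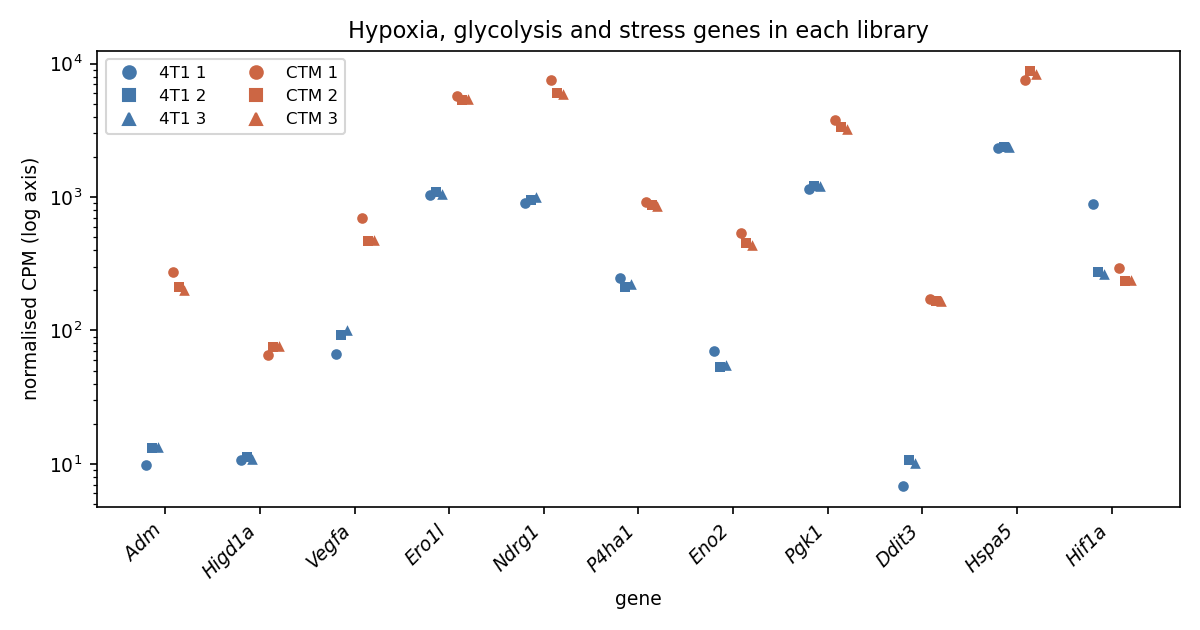
Normalised CPM on a log axis for 11 genes in each of the 6 libraries, blue for 4T1 and orange for CTM, with the marker giving the replicate number. For each gene except Hif1a the 3 CTM values lie above the 3 4T1 values, as for Adm with 200 to 274 CPM against 9.88 to 13.3.

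Glycolysis genes were higher as well. Of 17 members 13 rose and none fell (median log2 fold change 0.77, camera adjusted p = 1.54e-12 on the edgeR fit, 14 passing adjusted over the list alone), although the call was lost at an adjusted p = 0.321 with an estimated correlation. The neuronal enolase gene Eno2 was 8.0-fold higher, at 477 ± 50.2 against 59.6 ± 8.95 CPM (SD, n = 3 each), and Pgk1 was 2.89-fold and Gpi1 3.16-fold higher. Eno3, the muscle enolase gene, was outside the list and was 2.71-fold lower. Reads of Gapdh, Pgk1, Actb and the ribosomal protein genes may be shared with processed pseudogenes, so their levels are uncertain.

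In the list of unfolded protein and amino acid stress genes, 12 of 17 rose, 2 fell and 3 did not pass (median log2 fold change 1.10, camera adjusted p = 1.88e-08 on the edgeR fit, adjusted p = 0.327 with an estimated correlation, 12 higher and 2 lower adjusted over the list alone). Ddit3, the stress transcription factor CHOP, was 18.2-fold higher, at 168 ± 3.34 against 9.23 ± 2.08 CPM (SD, n = 3 each). Hspa5, the main chaperone of the endoplasmic reticulum, was 3.47-fold and Hsp90b1 2.47-fold higher. The 2 that fell were Psat1 and Phgdh, enzymes of serine synthesis, of which Psat1 was 2.80-fold lower.

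All 28 cell cycle genes fell, with a median log2 fold change of -1.44 (camera adjusted p = 6.31e-28 on the edgeR fit, adjusted p = 0.327 with an estimated correlation, 28 passing adjusted over the list alone). The replication helicase genes Mcm7 and Mcm4 were 2.58-fold and 2.91-fold lower, the replication clamp gene Pcna 2.51-fold lower and the mitotic cyclin gene Ccnb2 2.84-fold lower. Nuf2, a kinetochore gene outside the list, was at 16.1 ± 0.937 CPM in CTM and 57.7 ± 6.01 in 4T1 (SD, n = 3 each).

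Interferon response genes rose in 13 of 20 cases and none fell (median log2 fold change 1.56, camera adjusted p = 3.1e-08 on the edgeR fit, adjusted p = 0.327 with an estimated correlation, 18 passing adjusted over the list alone). Irf7, a transcription factor of this response, was 3.57-fold higher, at 45.6 ± 8.25 against 12.8 ± 2.76 CPM (SD, n = 3 each), and Rtp4 and Rsad2 were 4.19-fold and 4.15-fold higher. Of 10 genes of MHC class I presentation 7 rose and none fell (median log2 fold change 0.88, camera adjusted p = 0.00104 on the edgeR fit, adjusted p = 0.582 with an estimated correlation, 8 passing adjusted over the list alone), B2m being 2.28-fold and H2-D1 2.11-fold higher. None of the 6 measured MHC class II genes passed (camera adjusted p = 0.718).

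The mitochondrially encoded genes were lower in 11 of 13 cases (median log2 fold change -0.76, camera adjusted p = 2.24e-08 on the edgeR fit, adjusted p = 0.321 with an estimated correlation, 13 passing adjusted over the list alone), with mt-Nd2 2.06-fold lower. Nuclear genes of the respiratory chain fell in 11 of 28 cases and none rose (median log2 fold change -0.33, camera adjusted p = 0.00741, adjusted p = 0.615 with an estimated correlation, 11 passing adjusted over the list alone), Atp5b being 1.61-fold lower. Ribosomal protein genes rose in 19 of 32 cases and 1 fell, Rps2 (median log2 fold change 0.37, camera adjusted p = 0.000107, adjusted p = 0.793 with an estimated correlation, 22 higher and 1 lower adjusted over the list alone), Rpl22 being 2.28-fold higher.

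Among genes of adhesion and the cytoskeleton, Actb, the beta-actin gene, fell 2.96-fold, from 1684 ± 80.8 to 569 ± 8.87 CPM (SD, n = 3 each), and Tpm1, a tropomyosin gene, fell 2.25-fold. In the integrin and focal adhesion list 9 of 20 fell and 2 rose, Itga2 and Pxn (median log2 fold change -0.40, camera adjusted p = 0.0106 on the edgeR fit, adjusted p = 0.321 with an estimated correlation, 10 lower and 3 higher adjusted over the list alone). Itga3, an integrin of laminin binding, was 2.48-fold lower and Ilk 2.06-fold lower. Without 4T1 replicate 1 the call of this list was lost, at a camera adjusted p = 0.0778. Cholesterol synthesis genes fell in 7 of 17 cases and Sqle rose (camera adjusted p = 0.0183, adjusted p = 0.793 with an estimated correlation, 7 lower and 1 higher adjusted over the list alone), a call that was lost without 4T1 replicate 1, at 0.321.

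Most blood cell markers were at low levels in both groups. Of 21 platelet and megakaryocyte genes 8 were measured, of which 3 rose, none fell and 5 did not pass (median log2 fold change 0.81, camera adjusted p = 0.108 on the edgeR fit, adjusted p = 0.428 with an estimated correlation, 4 passing adjusted over the list alone). The risers were Itga2b, the platelet integrin subunit, at 8.16 ± 1.34 against 2.94 ± 0.217 CPM (SD, n = 3 each), Selp, which encodes P-selectin, at 142 ± 9.72 against 85.6 ± 12.7, and Gp1ba, at 0.646 ± 0.106 against 0.102 ± 0.0575. Pf4 and Ppbp, abundant platelet transcripts, were at 0.0883 ± 0.0647 and 0.935 ± 0.316 CPM in CTM and at 0.166 ± 0.12 and 1.04 ± 0.799 in 4T1 (SD, n = 3 each), with neither passing the test. By fry, which asks whether the list moves one way without comparing it with other genes, the adjusted p was 0.0246, and without CTM replicate 1 the camera adjusted p was 0.043. The fit without CTM replicate 1 was filtered anew. Low members seen in CTM replicates 2 and 3 could then enter, such as Plek at 1.30 and 1.13 CPM of the library total. With the libraries numbered 2 and 3 averaged, Itga2b, Selp and Gp1ba no longer passed, at edgeR adjusted p of 0.066, 0.0996 and 0.0797. That fit kept 475 of the 4575 calls over all genes, so this loss was not particular to platelet genes. Between the libraries numbered 1 alone the median log2 difference of the list was 0.08, and in those numbered 2 and 3 it was 0.77.

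None of 8 erythroid genes passed (camera adjusted p = 0.718). Of 7 neutrophil genes 2 fell (0.522), Mmp9 and Padi4, and of 13 pan-leukocyte genes 4 fell (0.718), namely Itgb2, Ptpn6, Lcp1 and Arhgdib. In the 4T1 culture the means were 2353 CPM for Mmp9 and 601 for Padi4. They were 194 for Itgb2, 106 for Arhgdib, 68.8 for Ptpn6 and 12 for Lcp1. Since the cultured line held these transcripts, their fall does not show fewer blood cells in CTM. Of 10 monocyte and macrophage genes 2 rose (0.718), Cd68 by 8.33-fold, at 351 CPM in CTM replicate 1 and 155 and 147 in the others, and Mrc1. The single measured T and NK cell gene, Lck, and the 3 B cell genes did not pass (0.867 and 0.718), and of 7 endothelial genes Cdh5 and Egfl7 fell (0.497). The B cell list passed without CTM replicate 1, at a camera adjusted p of 1.52e-06, with Igkc at 1.17 and 1.82 CPM in the other CTM libraries. The filter was applied anew to the remaining libraries and kept 17056 genes instead of 16414. B cell genes seen almost only in CTM replicates 2 and 3 could then enter, such as Ighm at 3.01 and 3.08 CPM of the library total. The list was thus not limited to the 3 genes above, and its pass is no separate support for a rise. Ptprc, the common leukocyte antigen gene, was at 0, 0.221 and 0.277 CPM in 4T1 and at 0.161, 1.079 and 1.339 in CTM and did not pass. In a count made after seeing the data, with genes too low for the filter included, CTM replicates 2 and 3 both lay above the other 4 libraries in 11 of 14 B cell genes and 9 of 20 pan-leukocyte genes, at no more than 3.079 and 3.565 CPM, and 4T1 replicates 2 and 3 did so in 0 and 4. For CTM it was 4 of 18 monocyte, 3 of 18 platelet, 2 of 15 T and NK cell, 0 of 13 neutrophil and 0 of 11 erythroid genes. For 4T1 these lists gave 0, 0, 1, 4 and 1. The share over all genes was not counted. Hepatocyte transcripts were present in all 6 libraries, Alb at 391, 370 and 376 CPM of the library total in 4T1 and at 306, 152 and 138 in CTM, a list added after seeing the data.

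**Figure D3:**
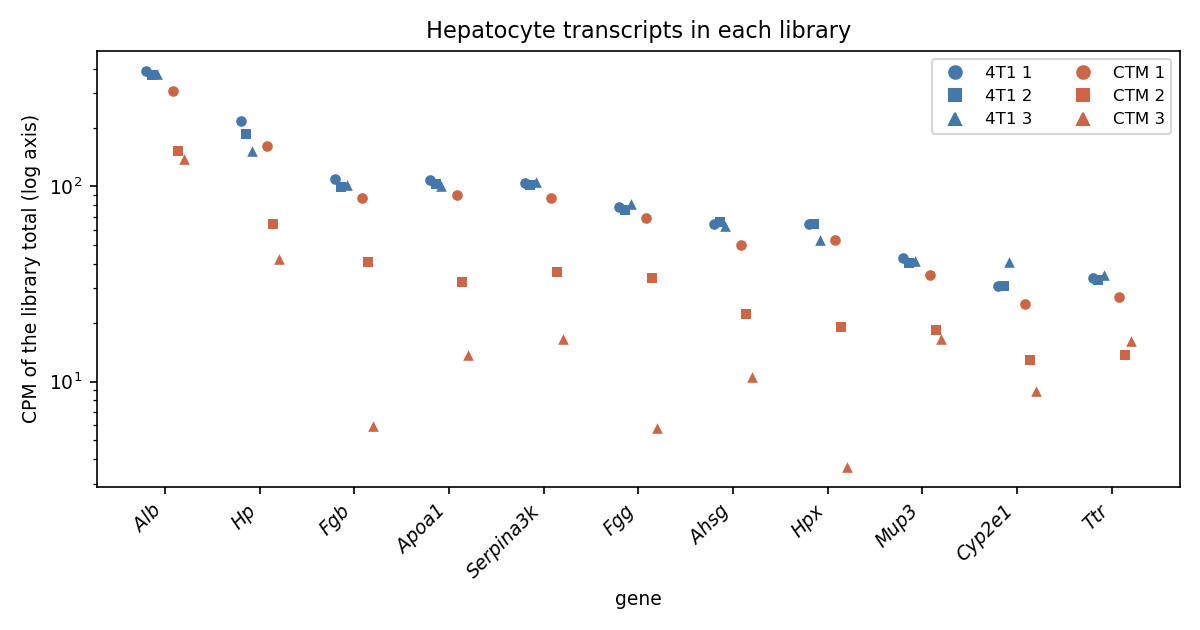
CPM of the library total on a log axis for 11 hepatocyte transcripts in each of the 6 libraries, blue for 4T1 and orange for CTM, with the marker giving the replicate number. Alb lies at 370 to 391 CPM in 4T1, at 306 in CTM replicate 1 and at 152 and 138 in CTM replicates 2 and 3, and Fgb falls to 5.9 in CTM replicate 3.

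Lists of cell identity moved in both directions and were not called. Of 16 epithelial genes 6 fell and 2 rose (camera adjusted p = 0.319), Krt7 falling 3.17-fold, Krt8 falling 1.36-fold, Krt19 rising 2.86-fold and Ehf rising, while Epcam stayed at 0.518 ± 0.159 against 0.462 ± 0.0347 CPM (SD, n = 3 each). Of 16 mesenchymal genes Vim, Fn1 and Snai1 rose and S100a4, Sparc, Cald1 and Mmp2 fell (0.718), Vim being 1.62-fold higher and S100a4 3.85-fold lower. Of 5 fibroblast genes 1 rose, Pdgfra, and 2 fell, Pdgfrb and Col1a1 (0.718), and of 18 junction genes 4 rose, namely Gja1, Pkp2, Pkp3 and Ppl, and 2 fell, among them Nectin2 (0.908), Gja1 being 2.41-fold higher. In the coagulation and fibrinolysis list 1 of 13 rose and 4 fell, F2rl1, Plau, F2r and Plaur (0.413). Plau, the urokinase gene, fell 3.56-fold, while F3, the tissue factor gene, was at 22.3 ± 2.13 against 19.1 ± 8.5 CPM (SD, n = 3 each) and did not pass. Of 18 immediate early and heat shock genes 4 rose, namely Atf3, Gadd45b, Junb and Ier3, and Fos, Fosb and Nr4a1 fell (0.718), Atf3 being 9.46-fold higher. Of 17 cytokine genes 4 rose, namely Ccl5, Il6, Il1a and Il1b, and Ccl2, Ccl20 and Csf1 fell (0.841), and of 7 stem cell genes Cd44 rose and Cd24a fell (0.867). The direction of the camera test differed from the sign of the median in the neutrophil, pan-leukocyte, monocyte, immediate early and cytokine lists, and the median and mean of the stem cell list differed in sign.

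**Figure D4:**
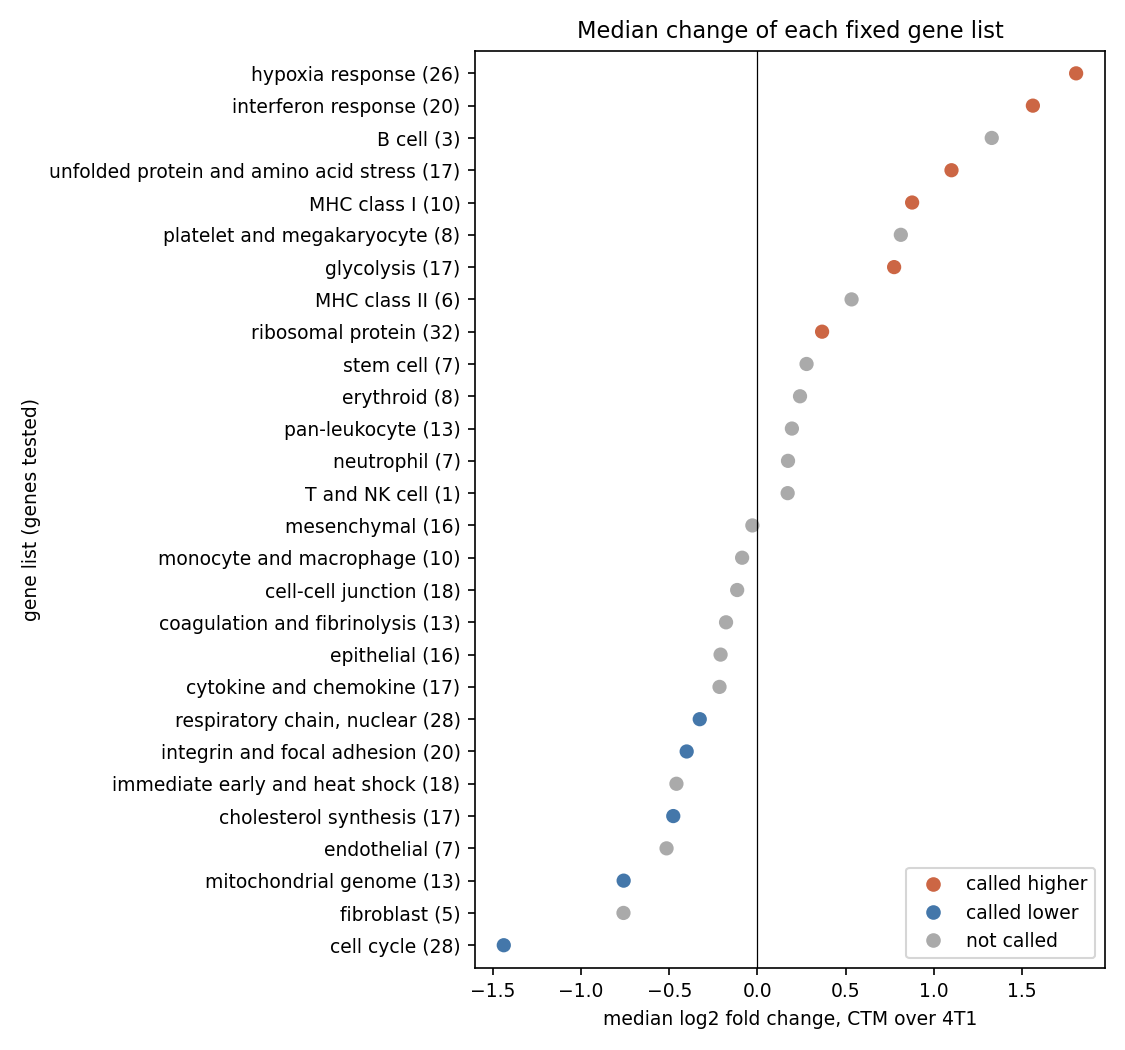
Median log2 fold change of CTM over 4T1 on the x axis for each of the 28 lists fixed before the data were examined, with the number of tested genes in brackets, orange for lists called higher, blue for lists called lower and grey for lists not called by camera at the preset correlation. The hypoxia response list lies at 1.80 and the cell cycle list at -1.44.

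The fixed rule named further genes. Nos2, the inducible nitric oxide synthase gene, rose 6.16-fold and P4hb, the protein disulfide isomerase gene, 3.60-fold. Arrdc3 rose 4.06-fold, Arrb1 4.29-fold and Fam162a 3.28-fold. Ankrd1, a target of YAP signalling, fell 9.10-fold, from 131 ± 7.02 to 14.4 ± 2.8 CPM (SD, n = 3 each), and Ngfr, the low-affinity neurotrophin receptor gene, fell 4.68-fold. Odc1, the rate-limiting enzyme of polyamine synthesis, fell 3.73-fold, Dglucy 3.01-fold, Ehd4 2.97-fold, Ttc8 2.95-fold and Tm4sf1 2.5-fold. The edgeR adjusted p of these genes lay between 0.000114 for P4hb and 0.000366 for Ttc8. Over all tested genes, the log2 differences between the libraries numbered 1 and those between the libraries numbered 2 and 3 correlated at r = 0.572, a correlation across genes, which are not independent replicates. Of the 4575 called genes 4572 had the same sign in both, but they were called on these same libraries. The median log2 differences of the 11 lists called by camera had the same sign in both, but several differed in size, at 1.69 between the libraries numbered 1 and 0.96 between those numbered 2 and 3 for the interferon response list, 1.42 and 0.74 for MHC class I, 0.42 and 0.78 for glycolysis, -0.92 and -1.55 for cell cycle and -1.03 and -0.15 for cholesterol synthesis.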

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

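The tests with counts divided by 4, without both libraries numbered 1, with a batch term and with the libraries numbered 2 and 3 averaged were chosen after seeing the data. Of the 4575 called genes, 4054 to 4575 were tested in each alternative, and none of those tested changed sign. Leaving out one library gave 1334 to 3323 genes higher and 1208 to 3326 lower, limma voom gave 4514 and 4628, the 2-fold minimum 738 and 832, and the fit without both libraries numbered 1 gave 4239 and 4340. With the libraries numbered 2 and 3 of each group averaged as 1 sample, which leaves 2 samples per group, 276 genes were higher and 200 lower and 475 of the 4575 calls were kept, while no list called before lost its call. The extremes were without CTM replicate 2 and without 4T1 replicate 1; leaving out 4T1 replicate 2 gave 1496 and 1415, 4T1 replicate 3 gave 1437 lower and CTM replicate 3 gave 1292 lower. The remaining alternatives stayed within 1.5 times, among them DESeq2 with 2647 and 2896. With library totals alone the median of all genes was -0.11 instead of -0.03 on the log2 scale, and 41% instead of 50.8% of the calls were higher. The hypoxia response list kept its call throughout, with camera adjusted p from 7.06e-79 to 0.0297. For the platelet and megakaryocyte list the values ranged from 0.043 to 0.334 on leaving out one library, fry gave 0.0246, and the others lay between 0.0741 and 0.428. The cause was not tested. The not called erythroid gene Slc4a1, at 7.47 CPM in 4T1 replicate 1 and 0.221 in both others, turned from a log2 fold change of -1.11 to 2.45 without that library (-1.65 to 2.45 on leaving out each library), to 2.44 under limma voom and to 2.70 without both libraries numbered 1, since that library alone set its 4T1 mean. The cholesterol synthesis list lost its call without 4T1 replicate 1 (0.321), without both libraries numbered 1 (0.354), with the batch term (0.0539) and by fry (0.138). The other lists called by camera kept their call by fry, which does not compare a list with other genes. Besides the hypoxia response list, their fry adjusted p ran from 0.00771 for the mitochondrial genome list to 0.0347 for the ribosomal protein list. The B cell list passed with no filter (0.0117) and without CTM replicate 1, 4T1 replicate 2 or 4T1 replicate 3. These fits let in low members seen almost only in CTM replicates 2 and 3. With the stricter filter the monocyte and macrophage list and the pan-leukocyte list passed (0.0445). Of the former only Cd68, which rose, reached that filter. Of the latter Itgb2, Ptpn6, Lcp1 and Arhgdib did, and all of them fell.

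Over all genes the replicate numbers did not tie the libraries of both groups, since deviations of same-numbered libraries correlated at 0.06, 0.02 and 0.01, although 2 genes switched between on and off with number 1. A replicate block gave 2232 genes higher and 2065 lower and kept 3865 of the 4575 calls, with a hypoxia response list adjusted p of 9.02e-52 and a platelet and megakaryocyte list adjusted p of 0.14. Depth limits markers below 1 CPM such as Pf4 and Gp1ba, where the low counts pile up at multiples of 4.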

Other observations

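The 5 lists reported here and the tests of liver transcripts, of the libraries numbered 1, of the summed blood transcripts, of zero counts among the lower genes and of the spread of single epithelial genes were chosen after the results were seen. The tests of chance, of blood cell lists, of depth and of dilution were planned. Genes of the lysosome rose in 11 of 20 cases and none fell (median log2 fold change 0.78, camera adjusted p = 1.59e-07 on the edgeR fit, adjusted p = 0.431 with an estimated correlation). In most members 4T1 replicate 1 was the highest 4T1 library. Its Neu1 was at 58.5 CPM against 17.3 and 17.2 in the other 4T1 libraries, and at 105, 65.9 and 65.1 in CTM. Lamp2, a lysosomal membrane protein gene, was at 562 ± 77.5 CPM in CTM and 217 ± 17.1 in 4T1, and Sqstm1, the autophagy receptor gene, at 1883 ± 121 and 826 ± 166 (SD, n = 3 each). Targets of actin and SRF signalling fell in 12 of 15 cases and none rose (median log2 fold change -0.75, camera adjusted p = 9.63e-09 on the edgeR fit, adjusted p = 0.0477 with an estimated correlation). Flna, the filamin gene, was at 614 ± 79.4 CPM in CTM and 1530 ± 111 in 4T1 (SD, n = 3 each).

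Targets of YAP and TAZ fell in 12 of 18 cases and 2 rose (median log2 fold change -0.85, camera adjusted p = 5.64e-06 on the edgeR fit, adjusted p = 0.0717 with an estimated correlation), with Ccn1 at 43.9 ± 8.98 CPM in CTM and 180 ± 13 in 4T1 (SD, n = 3 each). Serine and one-carbon genes fell in 7 of 11 cases and 3 rose (median log2 fold change -1.21, camera adjusted p = 0.0059, adjusted p = 0.713 with an estimated correlation). In all members 4T1 replicate 1 was the lowest 4T1 library. Its Shmt2 was at 95.5 CPM against 282 and 288 in the other 4T1 libraries, and at 63.3, 90.6 and 94.2 in CTM. These lists were prompted in part by genes already among the smallest p-values, namely Actb, Tpm1, Ankrd1 and Psat1. Without those genes the camera adjusted p was 1.45e-05 for actin and SRF targets, 0.000716 for YAP and TAZ targets and 0.09 for serine and one-carbon genes, so the last call was lost. With an estimated correlation and without those genes it was 0.132 for actin and SRF targets and 0.184 for YAP and TAZ targets, so neither passed. With all members, the fry adjusted p was 0.000113 for actin and SRF targets, 0.000164 for YAP and TAZ targets and 0.0217 for lysosome genes. The serine and one-carbon list, at 0.13, and the hepatocyte list, at 0.131, did not pass by fry.

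For the genes that differ between CTM and 4T1, 1 of the 10 splits of the 6 libraries, the real one, gave 4575 calls and the highest of the others gave 0, and 10 splits are too few for a share below 0.05. The planned test of blood cell RNA covered the pan-leukocyte, platelet and erythroid lists. It came out between its bounds, with a largest median of 0.81, for platelets. A median above 1 would have spoken for blood RNA, and below 0.5 in each of these lists against it. The B cell list was not part of this test, and the median log2 fold change of its 3 measured genes was 1.33. Blood RNA as a source of part of the rise therefore stays open. As the source of the whole rise, RNA of red cells, platelets, neutrophils and monocytes is argued against by a second test. This test was added after the outcome of the planned one. In it, 9 abundant transcripts of these cells summed to at most 25.6 CPM in a CTM library, against a rise of 167100 CPM over the higher genes. S100a8 alone made up 22.6 CPM of that sum, and the cultured 4T1 replicate 1 reached 24.6. The 9 transcripts include no lymphocyte gene, so the sum does not cover lymphocyte RNA. The planned test of depth set a median of 50.5 CPM in 4T1 for the lower genes against 17.1 for all. With thinning to the CTM depth it decided nothing, since the CTM totals averaged 100% of the 4T1 totals. Of the lower genes 1.33% were at 0 in a CTM library, so few were lost entirely. At their levels a count of 0 is unlikely even at a lower depth, so this share cannot decide on depth. The equal totals cannot either, since a fragment may be worth more than 1 count. Dilution as the sole cause of the epithelial differences is argued against, since 8 of the 12 genes at 10 CPM or more, a minimum set after the data were seen, lay over 2 SE from their median, with Krt7 at -1.66 (SE 0.16) and Krt19 at 1.52 (SE 0.29), while dilution as a part stays open, with an interquartile range of 1.03 between the planned bounds of 1 and 2.

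Hepatocyte transcripts made up 0.157%, 0.149% and 0.147% of the counts in 4T1 and 0.128%, 0.058% and 0.038% in CTM, and the list of 27 genes was lower in CTM with 1 gene, Cps1, passing (camera adjusted p = 0.000486, adjusted p = 0.713 with an estimated correlation). Over this list the median absolute log2 ratio of 4T1 replicate 1 to the other 4T1 libraries was 0.0766. That was below the lowest of 10000 random lists matched on CPM, at 0.109. Genes transcribed steadily by the 4T1 cells could also give this, so the test cannot exclude such transcription. A hypothesis is that liver RNA or reads from 1 outside source may be present in the 4T1 libraries and CTM replicate 1, where log2 ratios to 4T1 replicate 1 had an interquartile range of at most 0.19, and at a lower share in CTM replicate 2, at 0.43. The same mixture at a lower share is argued against for CTM replicate 3, at 1.18, where Fgb was at 5.9 and Alb at 138 CPM. What the source was, and whether liver cells were captured with the clusters, stays open.

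The libraries numbered 1 stood apart in both groups, and 4T1 replicate 1 held 153-fold more Muc1, 54.9-fold more Akr1b3 and 25.2-fold more Hspa1b than the mean of the other 4T1 libraries. A batch shared by both libraries numbered 1 is argued against as the cause of the general distance, since their deviations from the group means correlated at 0.06 over genes, which are not independent replicates. A processing difference shared by both libraries numbered 1 may still exist for a few genes, since 2 genes switched between on and off with number 1 and 0 did with number 2 or 3. Gm10260 was at 0 in both libraries numbered 1 and at 247 to 358 CPM elsewhere, and Gm26619 was at 188 and 289 CPM in them and at 0 elsewhere. No biological explanation was tested for this pattern.

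The unnamed gene ENSMUSG00000119584 was at 1405, 1620 and 1485 CPM of the library total in 4T1 and at 1773, 6475 and 6497 in CTM. Xist, too low to be kept by the filter, was at 0, 0.13 and 0.06 CPM of the library total in 4T1 and at 0, 5.44 and 1.69 in CTM, and whether it came from host cells was not tested. Both were singled out after their values were seen.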
